A study of Oncorhynchus mykiss with 31 samples.

How the data were processed

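Pituitary and head kidney RNA from rainbow trout (Oncorhynchus mykiss) was measured on 31 Agilent arrays. Per the labels' protocols, fish of about 118 g were acclimatised for 2 weeks, then held for 3 weeks while the mean temperature rose from 10.5 to 12.25 °C, and 150 ng of total RNA per sample was amplified and labelled with Cy3. Per the file headers and the submitters' processing notes, each array was scanned and read with Agilent Feature Extraction 10.7.3.1. The deposited array files hold the spot intensity in several columns per the file headers: the processed signal, which the scanner software has corrected for background, the mean pixel signal and the local background. No normalization between arrays has been applied to these intensities. The authors' series table holds log2 values. Set against the log2 processed signal, they differ by a single constant per array for 99.0% to 99.3% of probes, and every array has the same median of 6.65, so these values are the log2 signal centred on the median. The scale and centring were worked out from the values, and no column is left without a sample. Columns of flags from the scanner software, deposited with the intensities, marked spots as well above background, saturated or outlying.

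The main values were the log2 of the processed signal minus the log2 of the array's 75th percentile over non-control spots. Spots with an outlier flag were set missing, which removed between 10 and 396 spots per array. The 61657 spots were averaged into 60195 probes. A probe was tested in an organ where it was well above background on at least 50% of the arrays of either condition. Stressed and control fish were compared in each organ with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, on that organ's arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference of the effects between organs was a contrast of the 4 group means over all 31 arrays. Files were read with the packages data.table (version 1.17.8) and jsonlite (version 2.0.0).

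A gene name was taken only from the array files or, for 4 probes, from a RefSeq accession in them looked up in the gene table of the assembly USDA_OmykA_1.1. This gave 63 probes with a readable name, and 60132 probes kept their identifier. The 28 gene lists and marker lists fixed before the data were examined could not be tested as sets. Matching was by gene symbol, so a written-out name such as Catalase was not matched. Of these lists, 26 had no match, and the antioxidant and adipocyte lists had 3 and 1, under the minimum of 5 tested genes. For the same reason the corticotrope and steroid synthesis genes named in advance have no value here, and the cell composition of the organs was not analysed. In their place the readable names were sorted by what they say into groups of antioxidants, nuclear receptors, glucose metabolism, lipid metabolism, proteolysis and autophagy, and muscle and connective tissue. Groups with at least 5 tested probes were tested with camera at its preset correlation of 0.01 and with an estimated correlation, after missing values had been filled with the group mean. The mean of each group per fish was compared by an exact permutation test. The genes named in the text are, by the rule set in advance for comparisons with few calls, the 5 readable names with the smallest p in each direction. At most 2 identifiers per direction were added in the pituitary comparison, and a few are given in other comparisons. Names in the comparison of organs were chosen after their values were seen.

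For several probes near background, the arrays on which they were or were not well above background are given. All 16 fish carry 1 number each. The labels give a sample number, and the same number in the 2 organs was taken to mark organs of the same fish. No number is shared by stressed and control fish, so pairing bears only on the comparisons between organs. As a check, deviations from the group means over 41718 probes were correlated between organs. They correlated between 0.12 and 0.35 within 14 of the 15 fish, and at -0.02 in fish 50, whose pituitary array stands apart. In 13 of 15 fish the own pair had the highest correlation. The exceptions were fish 47 and 50, and the highest correlation of all, 0.583, joined the pituitary array of fish 50 to the head kidney array of fish 47, the 2 arrays with a compressed signal range. The consensus correlation within fish was 0.18 in the model with fish as a random block.

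The arrays lay on 6 slides, scanned on 2 days, with both conditions on every slide except for the head kidney arrays of slide 2, which were control only. The alternatives fixed before the data were examined were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, median centring, no filter and a strict filter on dim probes, slide and scan day as blocks, trended and robust variances, array weights, the series table, a joint fit of all arrays, the fish as a block, and leaving out each array. The closing section gives their effect. Added after the data were seen were the fits within each scan day, the slide as a random block in pituitary, the mean of both organs, the organ comparison and the name groups with their alternatives.

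The fits were tested on simulated data with 200 changed probes, drawn with the probes' own means and spreads. For the pituitary comparison of 47992 probes, 25.4% of changes of 0.5 log2 were called, 67.2% of changes of 1 and 92.4% of changes of 2. For the head kidney comparison of 45990 probes the shares were 14.9%, 67.2% and 86.4%. For the difference between organs over 43545 probes they were 11.9%, 56.7% and 84.8%. In the pituitary simulation camera gave an unadjusted p under 0.05 for 3 of 100 unchanged sets of 8 probes, and the head kidney simulation also gave 3 of 100. The simulated probes vary independently of each other. On the real pituitary arrays 21 of 99 other splits gave the antioxidant group an unadjusted camera p under 0.05, and 17 of 99 other splits of the fish did so for its difference between organs. The p-values of camera may therefore be too small for this group, and the exact permutation test over fish is given beside them.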

Results

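Pituitary and head kidney of rainbow trout were profiled on 31 single-colour arrays after 3 weeks in water of normal or deteriorated quality. The head kidney of a fish holds the interrenal cells that make cortisol, and the pituitary holds the corticotropes that drive them. The series addresses how this axis responds to a lasting environmental stressor. Stressed fish were kept at 3 to 4 mg/l oxygen in daytime, which the labels give as 30 to 40% saturation, and control fish at 8 to 12 mg/l, or 70 to 110% saturation. Each condition had 3 tanks, and organs were taken on day 21. The arrays comprised 8 stressed and 8 control pituitaries and 7 stressed and 8 control head kidneys. The sample number in each label was taken to name the fish, and on this reading 15 fish gave both organs. The tank of each fish is not given in the labels, so p-values over fish also carry any difference between tanks. The 75th percentile of the processed signal lay between 306 and 513 on the pituitary arrays and between 475 and 687 on the head kidney arrays. Between 59.2% and 85.9% of the 60195 probes were well above background on a pituitary array, and between 62.0% and 92.4% on a head kidney array. The number of arrays limits the precision of every value below. Levels are log2 signals relative to the array's 75th percentile. Nearly all probes carry only an assembly or read identifier, and 63 have a readable gene name. Some of these names are cut short in the files and are printed as they stand.

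In the pituitary of stressed fish, the antioxidant-related probes with a readable name were lower as a group. All 8 probes of the group had a lower mean in stressed than in control fish. The group holds Catalase, which breaks down hydrogen peroxide, the superoxide dismutases SOD1 and SOD2, the glutathione peroxidase GPX1, HPGPX1, the glutathione transferase GST, Nrf2, a transcription factor of antioxidant genes, and GR. The symbol GR is used for glutathione reductase as well as for the glucocorticoid receptor, and the files do not settle which is meant. The mean over the 8 probes was 2.13 ± 0.085 (SD, n = 8) in control fish and 1.93 ± 0.10 (SD, n = 8) in stressed fish, a 1.15-fold lower level. Each of the 8 stressed fish lay below the control mean, and 7 lay below the lowest control fish. A two-sided exact permutation test over fish gave p = 0.000311, or 0.00124 after Benjamini-Hochberg adjustment over the 4 name groups tested in this organ. The permutation treats fish as independent, although each condition had only 3 tanks and the tank of a fish is unknown. Within the first scan day the difference was -0.21 and within the second it was -0.19, each with an exact p of 0.0286, the smallest that 4 against 4 fish allow. The competitive test of limma, camera, gave an adjusted p of 0.000618 with its preset correlation and an adjusted p of 0.0110 with an estimated correlation. The adjusted p was 0.000516 without GR. Camera may understate the spread between fish for this group, since 21 of 99 other splits of the arrays also gave it an unadjusted camera p under 0.05.

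The members moved by small amounts. The log2 difference was -0.35 (SE 0.13) for GPX1, -0.31 (SE 0.12) for HPGPX1, -0.28 (SE 0.099) for Catalase and -0.16 (SE 0.083) for SOD2. GST differed by -0.22, Nrf2 by -0.15, SOD1 by -0.09 and GR by -0.06. GPX1, HPGPX1 and Catalase had unadjusted p-values of 0.0188, 0.0226 and 0.0127 in limma. None of the 8 passed the threshold over all 47992 tested probes, where the adjusted p was 0.378 for Catalase and 0.415 for GPX1. Of the antioxidant list fixed before the data were examined, only SOD1, SOD2 and GPX1 could be matched by symbol. Adjusted over the list alone, limma's p was 0.0564 for GPX1, 0.110 for SOD2 and 0.570 for SOD1 in pituitary, and 0.722 for each of the 3 in head kidney. The group of 8 was put together from the readable names after the files were opened, so it was not among the lists fixed in advance. All 8 stayed lower under each scaling and normalization tried, and 7 of 8 were lower without control fish 54, where the adjusted p of limma's camera was 0.00290.

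**Figure D1:**
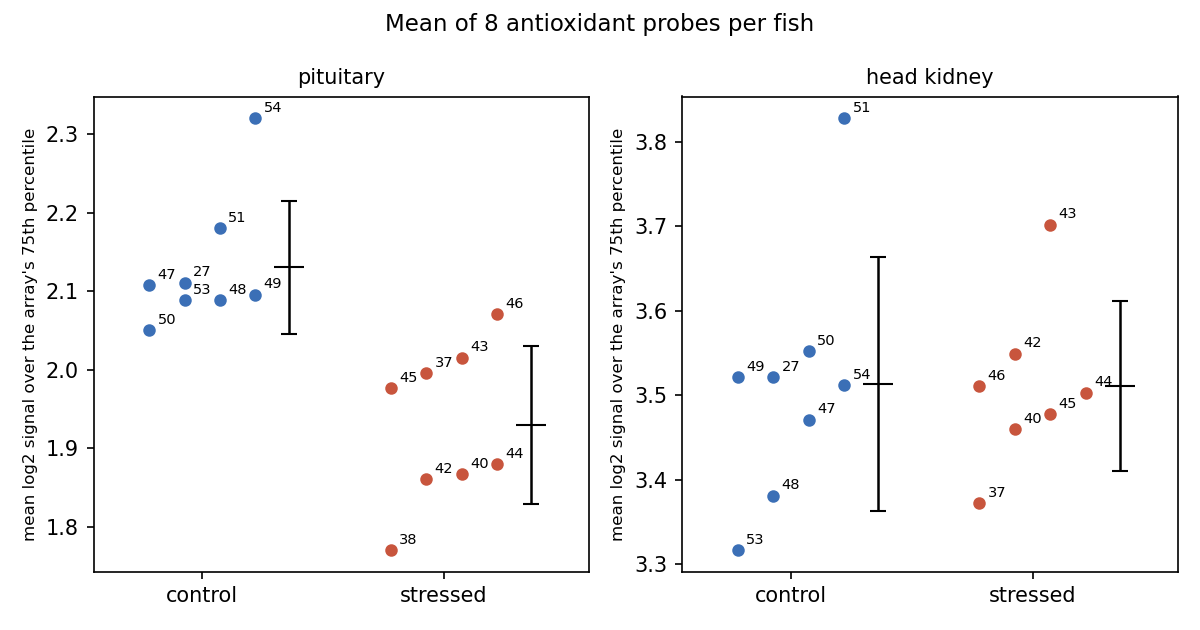
Each point is 1 fish, with its number, and gives the mean log2 signal of the 8 antioxidant probes relative to the array's 75th percentile in control and stressed fish, and bars show the group mean and SD. In the pituitary the 8 stressed fish lie between 1.77 and 2.07 and the 8 control fish between 2.05 and 2.32, while the head kidney groups overlap around a mean of 3.51.

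The same probes showed no such shift in head kidney. The mean over the 8 probes was 3.51 ± 0.15 (SD, n = 8) in control and 3.51 ± 0.10 (SD, n = 7) in stressed fish, with an exact permutation p of 0.968. In this organ 4 members were higher and 4 lower, with a median log2 difference of 0.02, a mean of -0.0022 and an upward direction in camera (adjusted p = 0.664). Head kidney Catalase differed by -0.54 (SE 0.25), from 2.10 ± 0.45 (SD, n = 8) to 1.56 ± 0.59 (SD, n = 7), with an adjusted p of 0.985 in limma. GPX1 and GST both had a positive log2 difference of 0.24 in this organ, and that of GST was -0.017 within the second scan day. The difference between the organs was tested on the 15 fish with both. The stress effect on the group was 0.18 log2 higher in head kidney than in pituitary, with an exact permutation p of 0.0311 over fish, unadjusted. Within the first scan day this was 0.16 (exact p = 0.171) and within the second 0.19 (exact p = 0.143). The camera test gave p = 0.0127, or p = 0.0333 with an estimated correlation, and 6 of 100 splits of the fish, the real one included, gave as small a camera p. Of the 8 members, 7 had the higher signed log2 change in head kidney.

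The other name groups did not pass the threshold in either organ. In pituitary, 7 of the 10 proteolysis and autophagy probes were lower and 3 higher, with a mean difference of -0.10 over fish (exact permutation p = 0.0819, adjusted p = 0.164). The camera test of limma gave an adjusted p of 0.144, and 0.322 with an estimated correlation. The same count was found in head kidney, where the group mean was 2.72 ± 0.071 (SD, n = 8) in control and 2.62 ± 0.086 (SD, n = 7) in stressed fish (exact permutation p = 0.0306, adjusted p = 0.122). The camera test gave an adjusted p of 0.604 for it, and 0.646 with an estimated correlation. Within the first scan day this difference was -0.11 (exact p = 0.0286) and within the second -0.10 (exact p = 0.200). In pituitary the corresponding differences were -0.18 and -0.02. LC3B, a protein of the autophagosome membrane, differed in head kidney by -0.32 (SE 0.16). Of the lipid probes, 6 of 9 were higher in stressed pituitary, and the camera test gave an adjusted p of 0.144. The 14 muscle and connective tissue probes tested in pituitary split into 7 higher and 7 lower, with an adjusted camera p of 0.767. Their median log2 difference was 0.04, their mean -0.0041 and the direction in camera upward. In head kidney the camera test gave an adjusted p of 0.607 for the lipid probes, with an upward direction although their median was -0.04 and their mean -0.11. It gave 0.604 for the muscle and connective tissue probes, 7 of 10 of which were lower. Within the second scan day the adjusted p of the latter group was 0.00349, with 9 of 10 lower, and within the first it was 0.921 with the direction turned. Without stressed fish 46 the pituitary proteolysis and autophagy group had an adjusted camera p of 0.0417, against 0.144 with all fish. Glucose metabolism and nuclear receptors had 3 and 4 tested probes in each organ, too few for a set test.

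Among single probes, 3 of 47992 differed between stressed and control pituitary in limma at an adjusted p under 0.05, with 1 higher and 2 lower. Unadjusted p-values under 0.05 were found for 4518 probes, where 2400 would be expected by chance. The probe that rose was TC96716, whose sequence reads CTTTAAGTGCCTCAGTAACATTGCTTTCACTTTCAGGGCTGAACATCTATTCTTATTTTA. Its level was -3.78 ± 0.78 (SD, n = 8) in control and -0.65 ± 0.88 (SD, n = 8) in stressed pituitary, a log2 change of 3.13 (SE 0.39, adjusted p = 0.0283). With normexp background correction and quantile normalization together the log2 change was 1.81, and with quantile normalization alone it was 3.14. All 8 stressed fish lay above all 8 control fish. The probe was well above background on 7 control and 8 stressed arrays. TC97829, with the sequence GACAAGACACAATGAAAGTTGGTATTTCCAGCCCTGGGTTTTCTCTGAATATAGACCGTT, fell from 1.37 ± 0.15 to 0.54 ± 0.28 (SD, n = 8 each, adjusted p = 0.043 in limma). CUST_22922_PI425536763, with the sequence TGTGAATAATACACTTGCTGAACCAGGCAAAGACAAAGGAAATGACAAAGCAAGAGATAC, fell from -0.53 ± 0.26 to -1.41 ± 0.24 (SD, n = 8 each, adjusted p = 0.043 in limma). The next probe by p, CUST_17410_PI425536763, was at -2.06 ± 0.21 in control and -1.29 ± 0.24 in stressed fish (SD, n = 8 each) and missed the threshold (adjusted p = 0.0582 in limma).

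No probe with a readable name was called in pituitary, and by the rule set before the data were examined the 5 with the smallest p in each direction are given as values. The probe named LDL differed by 0.26 (SE 0.081), the probe named trout by 0.27 (SE 0.086), and skelemin, a structural protein of muscle, by 0.90 (SE 0.31). The probe named lipoprotein differed by 0.64 (SE 0.27) and LOC100136786 by 0.15 (SE 0.078). Skelemin was well above background on 4 of 8 control arrays and lipoprotein on 5, so these differences rest on signals near background. In the downward direction the 5 were Catalase, GPX1, HPGPX1, SOD2 and atg4b, an autophagy protease, which differed by -0.51 (SE 0.26) and was well above background on 6 control and 2 stressed arrays. Over the 54 tested names alone the smallest adjusted p was 0.172, shared by LDL, trout, skelemin and Catalase. The count of 3 called probes was 2 within the first scan day, 0 within the second and 0 with scan day as a block. It was 2 with slide as a block. Leaving out single arrays gave 0 without stressed fish 37, 40, 43 or 46 or control fish 47, 49, 51, 54 or 27, and 1 without stressed fish 44 or control fish 53. It gave 5 without stressed fish 42 or control fish 48, and 15 without control fish 50, whose array had a compressed signal range (interquartile range 3.46 log2, against 4.17 to 4.93 on the other pituitary arrays).

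**Figure D2:**
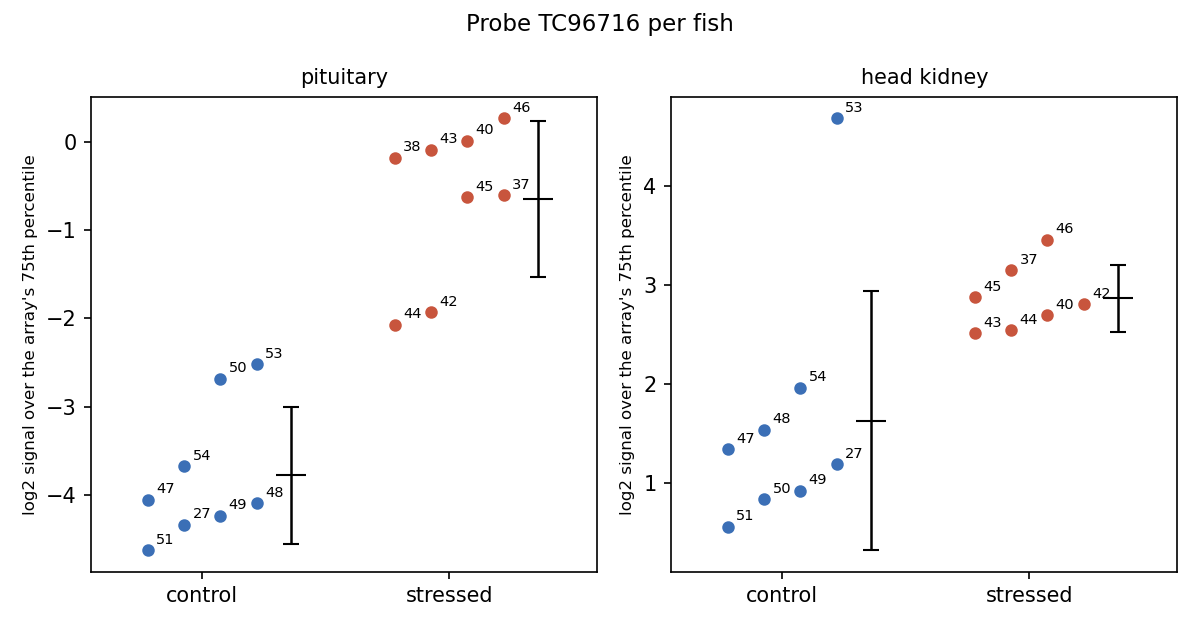
Each point is 1 fish, with its number, and gives the log2 signal of probe TC96716 relative to the array's 75th percentile in control and stressed fish, and bars show the group mean and SD. In pituitary all stressed fish lie above all control fish, and in head kidney control fish 53 lies at 4.69, above the 7 stressed fish at 2.51 to 3.46.

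In head kidney, limma called 0 of 45990 tested probes, and 2033 had an unadjusted p under 0.05 where 2300 would be expected by chance. The smallest adjusted p was 0.380. TC96716 was at 1.63 ± 1.31 (SD, n = 8) in control and 2.87 ± 0.34 (SD, n = 7) in stressed head kidney, a log2 difference of 1.23 (SE 0.48, adjusted p = 0.985). The control SD comes from fish 53 at 4.69, while the other 7 control fish lay between 0.56 and 1.97. Without that fish the difference was 1.67, with an adjusted p of 0.0643. The named probes with the smallest p in the upward direction were glucose transporter 1 at 0.25 (SE 0.11), the probe named fatty at 0.29 (SE 0.17), LOC100136786 at 0.17 (SE 0.11), GST and lipoprotein at 0.29 (SE 0.24). In the downward direction they were Catalase, LC3B, the probe named Serine at -0.46 (SE 0.22), and the myogenic factors myod1 at -0.43 (SE 0.23) and myogenine at -0.22 (SE 0.12). Serine was not well above background in stressed fish 43 and 45, which had its lowest values, -3.74 and -4.11. The same held for myod1 in stressed fish 40, its lowest at -4.93. None of the named probes passed, and the smallest adjusted p over the 48 tested names alone was 0.698. The count was 3 within the first scan day, 0 within the second, 0 with slide as a block and 2 when all 31 arrays shared 1 estimate of the spread. The array of control fish 47 had a compressed signal range (3.47 log2, against 4.50 to 5.36 on the other head kidney arrays), and without it the count was 0.

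The stress effect was then compared between organs probe by probe. limma found 0 of 43545 probes whose effect differed, and 1475 had an unadjusted p under 0.05. With each fish taken as a pair of organs, the count was 0 with the fish as a replicate block, whether as a random term (2184 probes under an unadjusted p of 0.05) or as the organ difference within each fish (2078 probes). Named probes with the smallest p and the higher effect in head kidney were GPX1 with a difference of 0.59 (SE 0.28), GST with 0.46 (SE 0.22), fatty with 0.35 (SE 0.20), HPGPX1 with 0.29 (SE 0.15) and calpain 1, a calcium-dependent protease, with 0.27 (SE 0.16). Those with the higher effect in pituitary were skelemin with -1.53 (SE 0.52), fbx32 with -0.49 (SE 0.32), Serine with -0.46 (SE 0.28), trout with -0.44 (SE 0.15) and LDL with -0.29 (SE 0.13). The higher effect here is the higher signed log2 change, not the larger response. Serine changed by 0.0002 in pituitary and -0.46 in head kidney, and HPGPX1 by -0.31 and -0.02. In control fish skelemin was well above background on 4 of 8 arrays of each organ. For fbx32 it was 6 of 8 pituitary arrays and all 8 head kidney arrays. Of the probes called in pituitary, TC97829 changed by -0.06 in head kidney and CUST_22922_PI425536763 by -0.08. Their differences were 0.77 (SE 0.16) and 0.80 (SE 0.25), and that of TC96716 was -1.89 (SE 0.63). These probes were chosen by their change in pituitary, which favours a difference. None of the differences passed the threshold.

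The organs themselves differed widely, which was tested in the 8 control fish with the fish as a replicate block, a comparison added after the data were examined. limma called 33245 of 50437 probes. Cyp1a3, a cytochrome P450 of xenobiotic metabolism, was higher in head kidney, at 1.84 ± 0.53 against -4.93 ± 0.91 (SD, n = 8 fish), with 2 of 8 pituitary arrays well above background. Pax7, a transcription factor of muscle precursors and pituitary melanotropes, was higher in pituitary, at 0.46 ± 0.22 against -5.70 ± 0.86 (SD, n = 8 fish), with 2 of 8 head kidney arrays well above background. Since most arrays of the dimmer organ were not well above background, no fold or ratio is given for these probes. Glucose transporter 1 was 4.99-fold and LC3B 2.97-fold higher in pituitary. The log2 ratio of pituitary over head kidney was 3.25 for the probe named fatty, and 2.46 with normexp and quantile normalization. For Wnt4b it was 3.32, with 6 of 8 head kidney arrays well above background, and 1.72 with normexp and quantile normalization.

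Of the antioxidant group, all 8 probes were higher in control head kidney than in control pituitary. GR was 7.38-fold, Nrf2 6.62-fold, GPX1 2.93-fold, GST 2.89-fold and Catalase 2.54-fold higher, and SOD1, SOD2 and HPGPX1 were 1.30-fold, 1.27-fold and 1.23-fold higher. The call was lost for SOD1 without the replicate block (adjusted p = 0.0642 in limma), and for SOD1 and HPGPX1 with normexp and quantile normalization (0.0884 and 0.334) and without fish 47 and 50 (0.0981 and 0.145). Probes of the proteolysis and autophagy group went both ways between the organs, and the group was not tested as a set. The probe named cathepsine was 4.95-fold, calpain 1 4.75-fold, calpain 2 2.55-fold and the proteasome subunit PSMA1 2.66-fold higher in head kidney. Calpastatin, the inhibitor of calpains, was 1.36-fold higher in pituitary, and LC3B was also higher there, while fbx32 and atg12l did not pass the threshold (adjusted p = 0.449 and 0.0915 in limma). The other probes named in this and the preceding paragraph had an adjusted p under 0.05 in limma. Centring on the median moved the median log2 difference of all probes from 0.0707 to -0.0627, so small differences depend on the scaling.

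**Figure D3:**
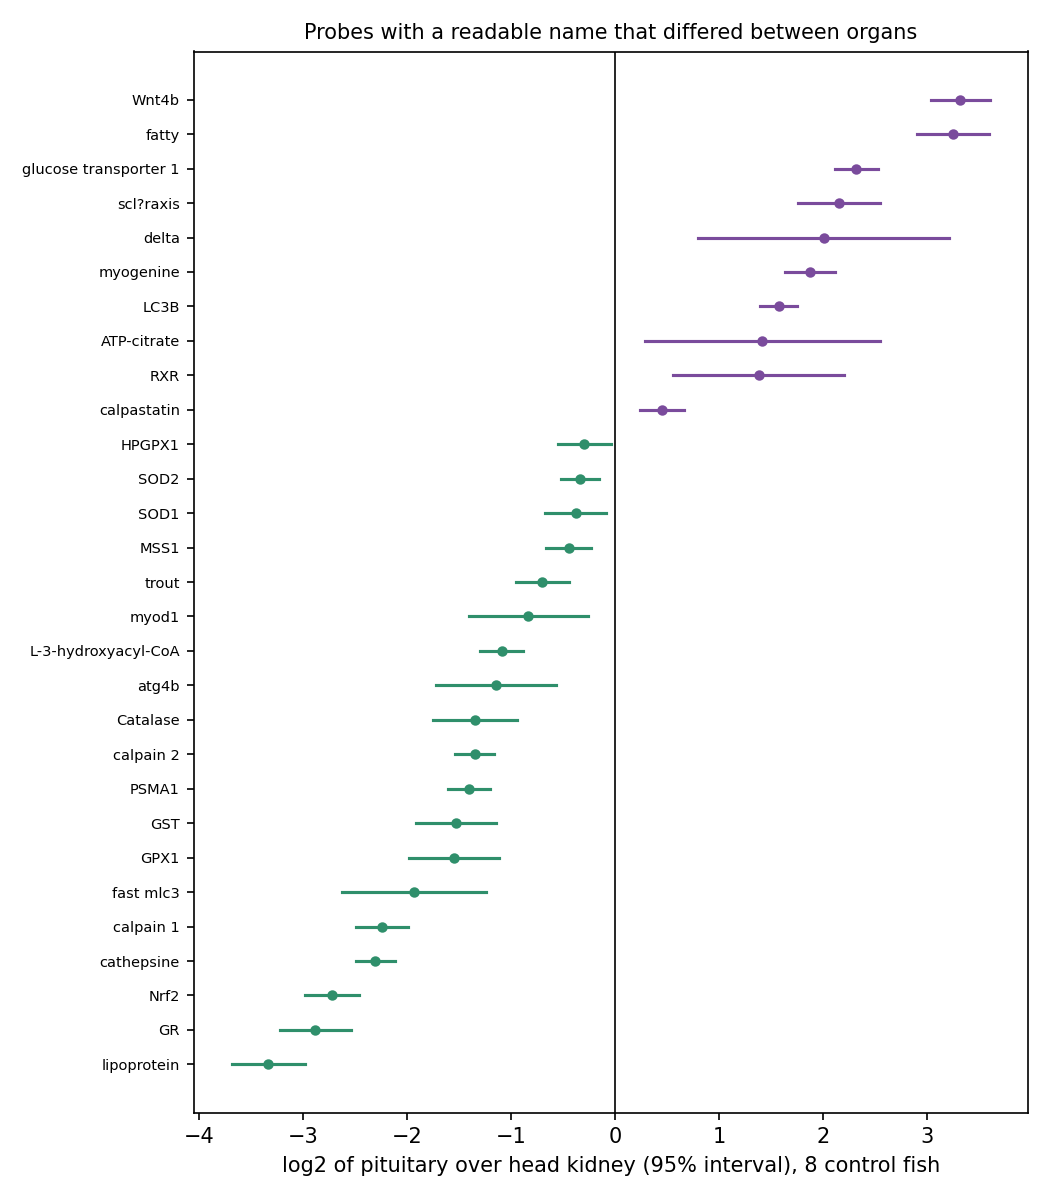
Points give the log2 ratio of pituitary over head kidney in the 8 control fish, with 95% intervals from limma, for the 29 probes with a readable name that had an adjusted p under 0.05 and were well above background on all 8 arrays of 1 organ and at least 4 of the other. The ratio was above 0 for 10 probes and below 0 for 19.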

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

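The tests in this part were chosen after the results were seen, except the counts over other splits of the pituitary arrays, the comparison with random probe sets of like brightness, the test for RNA of the other organ and the score of fish 53. The slide as a block was chosen for the pituitary comparison before the data were examined, but it was set as a test of TC96716 only after counts under it had been seen. An outlying sample was looked for in 74 sets of values, of which 16 were array measures and 58 were named probes in a group, and 9 were found where chance gives about 3.7.

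The antioxidant group had a camera p of 0.0127 for the difference of its stress effect between the organs. Of 100 splits of the 15 fish, 6 gave as small a camera p, the real one included, with 0.00028 for the most extreme other, so chance cannot be excluded for this difference. The group was lower in stressed pituitary. Brightness as the whole cause is argued against by random probe sets of the same brightness, since 0.96% of 10000 such sets had a mean as low as the observed -0.20. The compressed array of control fish 50 is argued against as well, since the adjusted p was 0.000493 without it, and so is the slide, since the adjusted p with slide as a block was 6.69e-05. Of 100 splits of the 16 pituitary arrays, 2 gave the group as small a camera p, the real one included. It was 0.000159 for the real split and 0.000129 for the most extreme other, so such a value was rare among splits of single fish. A chance difference between tanks is not covered by these splits, since the tank of each fish is unknown. A change of cell composition, a tank effect and a response of the pituitary to poor water all stay open, and a lower level of antioxidant transcripts under chronic low oxygen may be named only as a hypothesis.

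Probe TC96716 had an outlying value in head kidney control fish 53, at 4.69, where the nearest other control fish lay at 1.97. In pituitary fish 53 was also the highest of the 8 control fish, at -2.52, with fish 50 next at -2.68. An array of another fish under the number 53 is argued against by the correlation of 0.257 between the organs of fish 53, its highest among the 15 fish. Whether the whole fish stands under the wrong condition cannot be told apart from the data, because a score built from the other fish, which put fish 53 at -0.248 on the control side, placed only 12 of the other 15 fish on their own side. For the rise in pituitary, the slide as the whole cause is argued against by a change of 3.06 with slide as a block. What sets the level of this unnamed probe stays open, with stress, tank and inherited differences between fish among the possibilities.

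The signal range was outlying on the array of head kidney control fish 47, with an interquartile range of 3.47 log2, and on that of pituitary control fish 50, with 3.46 log2. The latter also had an outlying 75th percentile of 513. The deviations of these 2 arrays correlated at 0.583, above the highest correlation between organs of the same fish, 0.351. A raised local background is argued against, since 0 of the 2 arrays lay above the others of their organ in median local background. RNA of the other organ is argued against, since probes of the other organ rose by at most 0.117 log2 more than equally dim undetected probes. On the array of fish 47, probes not detected on any other array rose by 1.56 log2, more than on every other head kidney array. Control probes of spike-in sequences rose by 2.49 there. The negative control probe did not go along, with a signal of 32.1 within the 28.2 to 33.5 of the other head kidney arrays. Unspecific signal is thus undecided for this array. On the array of fish 50 the spike-in probes rose by 2.01. The negative control probe read 35.4 there, above the 29.8 to 34.8 of the other pituitary arrays. The undetected probes rose by 0.926, within the other pituitary arrays, so unspecific signal cannot be told apart from other causes there. The test of undetected and spike-in probes was first made jointly on both arrays. It asked for a rise above 1 log2 and above all other arrays on each, and that joint criterion was not met. The separation by array was made after that outcome was seen, so unspecific signal on the array of fish 47 is only a hypothesis. No biological explanation was tested.

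The head kidney array of control fish 53 had 299 outlier spots, where the next control array had 151. CUST_22922_PI425536763 lay at -0.87 in pituitary of stressed fish 38, where the nearest stressed fish lay at -1.34. Catalase lay at 1.14 in pituitary of control fish 51, above the next at 0.80. GPX1 lay at 2.96 in pituitary of control fish 27, below the next at 3.43. Myogenine lay at -3.44 in head kidney of stressed fish 45, below the next at -2.91.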

How the results depend on the processing

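The alternatives of the name groups, the mean of both organs and the organ comparison, the fits within scan days, the slide as a random block in pituitary and the difference without the 2 compressed arrays were chosen after seeing the data; the others were planned. The pituitary count of 3 called probes became 19 with normexp and quantile normalization, 1 without a filter, 0 with scan day as a block, 0 within scan day 2, 9 with trended and robust variances, 22 with array weights and 13 with all 31 arrays in 1 fit. The other settings gave 2 to 4. Leaving out 1 array gave 0 to 15: 0 without stressed fish 37, 40, 43 or 46 or control fish 47, 49, 51, 54 or 27, 1 without stressed fish 44 or control fish 53, 5 without stressed fish 42 or control fish 48, and 15 without control fish 50. The cause of these changes was not tested. TC96716 kept its direction under all 29 alternatives that tested it, with a change of 1.81 to 3.33 and an adjusted p of 0.00195 to 0.771, and it passed the threshold under 17. The strict filter left it out, and its call ended with scan day as a block (0.0637), within each scan day, and in the 9 leave-one-out fits that called 0 probes. TC97829 passed under 11 of 30 and CUST_22922_PI425536763 under 12 of 30. Of 100 splits of the pituitary arrays, 2 called as many probes, the real one included. The real split had 3 calls and the highest other 30. As many probes under an unadjusted p of 0.05 came from 2 splits, with 4518 in the real one and 5591 in the highest other. Such counts were thus rare among splits of single fish. These splits took no account of tank or scan day, so they cannot exclude a chance difference between tanks. The split with 30 calls made several times the real count. Such a count can come with a structure among the samples, which was not tested beyond the scan day, on whose side 8 of the 16 arrays of this split lay.

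The head kidney count of 0 became 3 within scan day 1 and 2 with all 31 arrays in 1 fit, and was 0 under every other alternative, each left-out array included. A real count of 0 is reached by all 100 splits by construction, so the splits say nothing about chance here. The highest other had 14 calls. The difference between organs stayed at 0 probes under all 44 alternatives, the fish as a replicate block included, which changed no call of a named probe there, and the 100 splits, with 38 calls in the highest other, say nothing about chance for a count of 0 either. The mean of both organs, at 0, became 5 with normexp and quantile normalization, 3 with the strict filter, 2 without fish 42 and 1 without fish 40, 44 or 53. The antioxidant group in pituitary kept its direction and its call under all 28 alternatives, with an adjusted camera p of 6.69e-05 to 0.0183. These p-values may be too small, since 21 of 99 other splits of the arrays gave the group an unadjusted camera p under 0.05. Over the 14 probes named in pituitary, 49 of 416 values lost the call and 6 gained one. Only the 3 called probes could lose it. TC96716 lost it under 12 of 29 alternatives, TC97829 under 19 of 30 and CUST_22922_PI425536763 under 18 of 30. The set direction of groups without a call turned in several cases, with adjusted p-values of 0.873 (normexp), 0.927 (quantile), 0.998 (scan day 2) and 0.870 (without stressed fish 43) for antioxidants in head kidney, 0.757 (without stressed fish 37) and 0.917 (without control fish 48) for muscle and connective tissue in pituitary, and 0.921 (scan day 1) and 0.877 (without control fish 53) in head kidney. Over the left-out arrays these ranged from 0.415 to 0.980, from 0.396 to 0.986 and from 0.0652 to 0.877. GST in head kidney turned to -0.017 within scan day 2. The gene lists fixed in advance were not run under any alternative, because fewer than 5 genes of any list could be matched by symbol. Signal over background limits the probes near the floor, such as skelemin and lipoprotein.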

Other observations

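The tests in this part were chosen after seeing the data, except the counts over other splits. In the control fish the organs separated by more than any of the other relabellings of the paired organs drawn, with 33245 called probes in the real split and 17560 in the highest of the other 99 splits, and 1 of 100 splits as large, the real one included. Without the replicate block the count was 32225, and without fish 47 and 50 it was 32663.

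Averaging both organs of each of the 15 fish gave 0 called probes of 43545 in limma, with 3107 under an unadjusted p of 0.05. The count was 5 with normexp and quantile normalization and 3 with the strict filter, and leaving out single fish gave 2 without fish 42, 1 without fish 40, 44 or 53 and 0 otherwise. A real count of 0 is reached by all 100 splits of the fish by construction, so they say nothing about chance. The highest other had 36 calls. The smallest adjusted p in limma was 0.0799, shared by TC108874 with a change of -0.83 and CUST_14002_PI425536763 with -0.78. TC96716 is given because it was called in pituitary, and other probes had a smaller p here. Its change in this mean was 2.15 (SE 0.38, adjusted p = 0.189 in limma). Without fish 53, the control fish with its outlying head kidney value, the change was 2.45 (adjusted p = 0.00336 in limma). TC96716 passed the threshold under 1 of 19 alternatives. The stress effects correlated between organs at r = 0.32 across probes, which are not independent replicates. Of 100 splits of the fish, 23 gave as high a correlation, up to 0.43, so chance cannot be excluded.

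Many probes followed the fish from organ to organ. Over 15 fish, 809 of 41718 probes had a correlation above 0.9 between pituitary and head kidney after removal of the group means. Condition and scan day do not account for this, since 100 shuffles of the fish within condition and scan day gave at most 92 such probes, and 0 fish had both arrays on 1 slide. The values of these probes spanned a median range of 2.36 log2 between fish, against 0.90 for as many other probes drawn at random. The range exceeded 4 log2 for 183 of them, against 10. A wider range was largely fixed by the choice of probes and is no separate evidence. A correlation above 0.9 needs a spread between fish that is large against the noise. In the pituitary comparison 0 of the 809 were called, and 0 of the random probes. Since only 3 of all 47992 tested probes were called, this count says nothing about a response to stress. Inherited differences between fish, such as variants under the probe or deleted gene copies, may lie behind these probes, which was not tested because the probes have no gene name or position here. The tank, or any other state shared by both organs of a fish, may do so as well. The shuffles held only condition and scan day fixed, so they cannot tell these apart.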
